A study of Mus musculus with 56 samples.

How the data were processed

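Microglia and astrocytes were sorted from the whole brains of 28 female mice, and RNA from each sort was made into a 3′ tag sequencing library. Per the labels, the mice carried either wild-type (WT) Trem2 or a homozygous knockout (KO), and were young (2 months) or old (16 to 18 months). Microglia were the Cd11b-positive cells and astrocytes the ACSA-2-positive cells. Each of the 8 groups of cell type, genotype and age held 7 libraries, 56 in all. Each mouse gave 1 library of each cell type, since the labels give both sorts the same animal number. Per the labels' protocols, libraries were made from low RNA inputs with a kit that reads the 3′ ends of mRNA and adds unique molecular identifiers (UMI).

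The deposited table holds whole-number counts per gene for 53801 Ensembl gene identifiers, with no normalization by the authors. Per the submitters' processing notes, FastQC 0.11.5, STAR, MultiQC and R 3.4.3 were used with the mouse build GRCm38.p6. The counting program, the annotation release and whether reads with the same UMI were collapsed are not given in the sources used here. The counts are therefore read as counts, and not as molecules. Gene names and positions were taken from GENCODE M21, which matched 53620 of the identifiers. Identifiers sharing a symbol numbered 128, and all genes were analysed by identifier. A 3′ tag count compares a gene between libraries and carries no gene length correction.

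Total counts per library ran from 200710 to 1034874, and counting error is only part of the spread. Across 168 pairs of replicates, the chi-square per degree of freedom against counting error alone ran from 1.64 to 11.7. All tests therefore used the spread between mice. Values per library are CPM, counts scaled to a common library size with the trimmed mean of M-values (TMM), given as mean ± SD over 7 mice.

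Comparisons were fitted with edgeR 4.0.16 in R 4.3.3, using TMM, filterByExpr, the quasi-likelihood F-test and Benjamini-Hochberg adjusted p under 0.05. The 28 libraries of a cell type were fitted together with 1 mean per group. From each fit came KO against WT at each age, old against young in each genotype, and the genotype by age interaction. All 56 libraries were fitted together for 4 further comparisons between cell types, which makes 14 in all. The numbers of genes tested were 7512 in microglia, 7524 in astrocytes and 9434 across both. Log2 fold changes of genes are given ± their standard error. The 38 gene lists, of which 24 are pathways or cell states and 14 are markers of cell types, were tested with camera from limma 3.58.1 at a preset correlation of 0.01. An estimated correlation per list was the stricter alternative, and an adjusted p said to be with an estimated correlation comes from it. Marker levels per library were compared with exact two-sided permutation tests over all 3432 splits of 7 against 7. The smallest possible p is 5.83e-04. The main measure was the mean log2 level of a list, and the log2 of its summed CPM was the alternative. A p given beside a summed level is from that log2 sum. Of 112 marker tests, 0 passed the adjusted threshold with either measure.

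The groups, comparisons, lists, tests and alternative settings were chosen before the data were examined, as was the rule for naming genes. In each comparison it takes, among genes past the threshold with a mean log2 CPM of at least 3 and a proper name, up to 8 with the largest rise and up to 8 with the largest fall. It adds up to 4 members of each list with at least 3 members past the threshold. Trem2, Treml1, Apoe, Abca1, Abcg1, Ch25h, Lpl, Cst7, Itgax and Clec7a are followed in microglia, and Gfap, Serpina3n, C4b, Lcn2, C3 and Apoe in astrocytes, whatever their p.

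The alternative settings were median-of-ratios scaling (RLE), no filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, and a fit to only the 2 groups compared. Further ones were each library left out in turn, the RNA integrity number (RIN) as a covariate, sets of 4 consecutive animal numbers as a covariate, and the animal as a block in comparisons between cell types. For lists, fry was run beside camera. Covariates for marker levels and for reads of processed gene copies, and fits without some libraries or genes, were added after the data were seen. No batch is given in the labels, and no library was left out of the analysis. The RIN is missing for 1 library.

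Pairing by animal was checked by correlating the 2 cell types of each mouse over 4538 genes after removal of group means. The median correlation was 0.158 within mice and 0.00809 between mice, and 19 of 28 mice exceeded 0.1 with themselves. For 4 of the 28, the best match was the mouse itself, so the check is weak and the pairing rests on the labels.

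The models were tested on simulated data with known changes in many genes at once. With few changed genes the adjusted threshold is stricter, so the shares found here hold for many. For KO against WT in old microglia, 13.6% of genes changed 1.5-fold, 74.2% of those changed 2-fold and 100% of those changed 4-fold were called, with 7 false among 130 calls. In old astrocytes the same shares were 13.9%, 72.7% and 100%, with 3 false among 126 calls. The interaction recovered 38.8% of 2-fold and 89.2% of 4-fold changes, with 6 false among 97 calls. The difference between cell types recovered 35.5% and 88.3%, with 4 false among 81 calls. A list with 31 members changed 1.3-fold was called at adjusted p = 5.89e-27, and 0 of 26 lists without a changed member were called. The simulated genes were drawn independently, so this says nothing about false calls of lists whose members move together.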

Results

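The series measured gene expression by 3′ tag counts in microglia and astrocytes of WT and Trem2 KO mice at 2 ages, with 7 mice in each group. Trem2 is a lipid-sensing receptor of microglia, and the design asks how its loss changes both cell types in young and old brains. Median total counts per library in microglia were 668302 in young WT, 606481 in young KO, 548888 in old WT and 606699 in old KO mice. In astrocytes they were 571786, 581936, 454815 and 585727. The lowest total, 200710, was an old KO microglia library (animal 8), and the highest, 1034874, a young WT microglia library (animal 1). The 2 mitochondrial ribosomal RNA genes took a mean of 16.0 to 18.6% of counts in the astrocyte groups and 7.47 to 9.80% in the microglia groups.

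Trem2 (ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147, plus strand, GRCm38) fell in KO microglia at both ages. Its level was 465 ± 127 CPM in young WT, 99.3 ± 28.9 in young KO, 470.1 ± 101 in old WT and 116 ± 31.5 in old KO microglia (SD, n = 7). Every KO library lay below every WT library, with a highest KO value of 174 CPM and a lowest WT value of 296 CPM. The log2 fold change was −2.23 ± 0.18 in young and −2.02 ± 0.18 in old microglia. Counts in KO microglia were well above the astrocyte group means of 5.45 to 9.34 CPM. The highest of these means, in old KO astrocytes, rests on animal 12 at 35.5 CPM, and the other 6 libraries were at 9.72 CPM or less. The targeted allele is not given in the labels and a 3′ tag may lie outside the deleted part, so the remaining Trem2 counts say nothing about protein. The neighbouring gene Treml1 was low in all microglia groups, at 3.68 to 5.44 CPM. In astrocytes no Trem2 effect can be read at this level.

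In young microglia, loss of Trem2 lowered the phagocytic lectin receptor gene Clec7a from 56.5 ± 4.34 to 23.2 ± 6.75 CPM (SD, n = 7). Cd34, a surface sialomucin gene, fell from 191 to 123 CPM, and no gene rose past the threshold with these settings. In total 4 genes were called, all lower in KO, and 510 had an unadjusted p under 0.05. Besides Trem2 (adjusted p = 1.1e-10), these were Clec7a (ENSMUSG00000079293.11, chromosome 6, 129461591 to 129472779, log2 −1.26 ± 0.17, adjusted p = 4.0e-05), Cd34 (−0.64 ± 0.12, 0.0154) and the haemoglobin gene Hbb-bs (−3.58 ± 0.71, 0.0247). Hbb-bs fell together with the other red cell markers, whose summed level was 73.2 ± 66.7 CPM in WT and 5.45 ± 8.15 CPM in KO (exact permutation p = 0.00525, adjusted p = 0.147 over 112 marker tests). In young astrocytes red cell markers summed to 56.9 ± 64.0 CPM in WT and 11.7 ± 12.8 CPM in KO (exact permutation p = 0.644, adjusted p = 0.933). The lower mean was thus not particular to microglia. In young microglia border macrophage markers summed to 1454 ± 234 CPM in WT and 1813 ± 385 CPM in KO (exact permutation p = 0.0659, adjusted p = 0.388; as a list, adjusted p = 0.635 with an estimated correlation). T and NK cell markers summed to means of 28.2 and 45.2 CPM (exact permutation p = 0.0169, adjusted p = 0.237), and neutrophil markers to 544 ± 125 and 723 ± 241 CPM (exact permutation p = 0.0868, adjusted p = 0.442). By mean log2 level, exact permutation p was 0.171 for border macrophage, 0.0146 for T and NK cell and 0.0181 for neutrophil markers. The adjusted p were 0.527, 0.149 and 0.149. Genes of the second stage of disease-associated microglia, the Trem2-dependent state seen around plaques and in ageing, were lower as a list. Of 19 tested, 17 had a negative log2 fold change, 1 was called lower, and 3 were lower when adjusted over the list alone (median log2 −0.36, adjusted p = 2.2e-05 with an estimated correlation). Lpl (−0.73 ± 0.20, adjusted p = 0.541), Cst7 (−1.41 ± 0.56), Itgax (−0.78), Apoe (−0.13), Abca1 (−0.02) and Abcg1 (0.45) were not past the threshold. Calls numbered 2 with a border macrophage covariate, with only the 2 groups fitted, or without any 1 of KO animals 14, 18 and 22 or WT animal 21. They numbered 7 with numbering sets as a covariate, 2 of them higher in KO, and 63 without the filter, 40 of them higher.

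In old microglia, loss of Trem2 lowered Lpl, Spp1, Clec7a and Axl, genes of lipid handling and activation that were higher in old than in young WT microglia. Lipoprotein lipase (Lpl, ENSMUSG00000015568.16, chromosome 8, 68880491 to 68907448) was at 437 ± 80.4 CPM in old WT and 44.9 ± 20.4 CPM in old KO microglia. Osteopontin (Spp1, ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050) was at 325 ± 115 and 11.3 ± 5.89 CPM. For both genes every old KO library lay below every old WT library. The lowest old WT values were 321 CPM for Lpl and 208 CPM for Spp1, against highest old KO values of 75.7 and 18.5 CPM. Clec7a fell from 169 ± 27.01 to 60.4 ± 14.8 CPM. Axl, a receptor kinase for apoptotic cells (ENSMUSG00000002602.16, chromosome 7, 25757273 to 25788705), fell from 127 ± 22.9 to 51.8 ± 9.53 CPM.

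In old microglia 10 genes were called, 1 higher and 9 lower in KO, and 342 had an unadjusted p under 0.05. The falls were Spp1 (log2 −4.71 ± 0.32, adjusted p = 1.5e-13), Lpl (−3.24 ± 0.20, 1.6e-14), Trem2 (9.3e-10), the protease inhibitor gene Cst7 (−1.80 ± 0.32, 0.00259), the sialyltransferase gene St8sia6 (−1.75 ± 0.26, 8.9e-05), Clec7a (−1.53 ± 0.15, 3.8e-09), Axl (−1.26 ± 0.20, 3.0e-04) and the surface glycoprotein gene Cd52 (−0.78 ± 0.15, 0.00897). Tns1, a focal adhesion gene outside the naming rule and chosen after its values were seen, was the other (−0.65 ± 0.14, 0.0250). The 1 rise was the macrophage transglutaminase gene F13a1 (ENSMUSG00000039109.16, chromosome 13, 36867178 to 37050244), from 228 ± 56.8 to 385 ± 58.3 CPM (log2 0.75 ± 0.15, adjusted p = 0.00897).

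Calls numbered 16 with numbering sets as a covariate (3 higher), 16 with DESeq2 (4 higher), 18 with a copy-to-parent covariate (4 higher), 26 without the filter (7 higher) and 6 with a border macrophage covariate (0 higher). The copy-to-parent covariate tracks reads of processed gene copies.

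Gene lists in old microglia were compared in the same way. Of 19 second-stage genes 6 were lower in KO past the threshold, and 10 when adjusted over the list alone (median log2 −0.50, adjusted p = 3.3e-13 with an estimated correlation). The 9 first-stage genes had negative log2 fold changes, none past the threshold (median −0.17, adjusted p = 0.149 with an estimated correlation), and Apoe (1731 against 1320 CPM, log2 −0.39 ± 0.14, adjusted p = 0.742) was not called. Homeostatic genes were higher as a list (median 0.18, adjusted p = 0.0255 with an estimated correlation), with 19 of 22 positive and none called singly. The cholesterol transport list was lower by its mean (−0.20, adjusted p = 0.00319 with an estimated correlation), while its median was 0.12. The mean was carried by Lpl (−3.24), the 1 member called, and Abca1 (−0.05) and Abcg1 (0.22) were not. Border macrophage markers were positive in 8 of 9, with 1 higher past the threshold and 4 when adjusted over the list alone (median 0.43, adjusted p = 0.0125 with an estimated correlation). Their summed level was 1413 ± 201 CPM in old WT and 1924 ± 222 CPM in old KO microglia (exact permutation p = 0.00175, adjusted p = 0.0979). Ribosomal protein genes had negative log2 fold changes in 19 of 23 (median −0.17, adjusted p = 0.0518 with an estimated correlation). Their mean share of counts was 1.60% in old WT and 1.47% in old KO microglia. The latter includes animal 20 at 1.16%, with the nearest other at 1.45%. F13a1 is itself 1 of the border macrophage markers, so a covariate of their level says little about it (log2 0.35, not called), and without animals 5 to 8 it was at 0.72 (adjusted p = 0.0659). Cst7 (−1.71, adjusted p = 0.445) and Cd52 (−0.78, adjusted p = 0.214) were also not called with that covariate, at folds close to those without it.

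**Figure D1:**
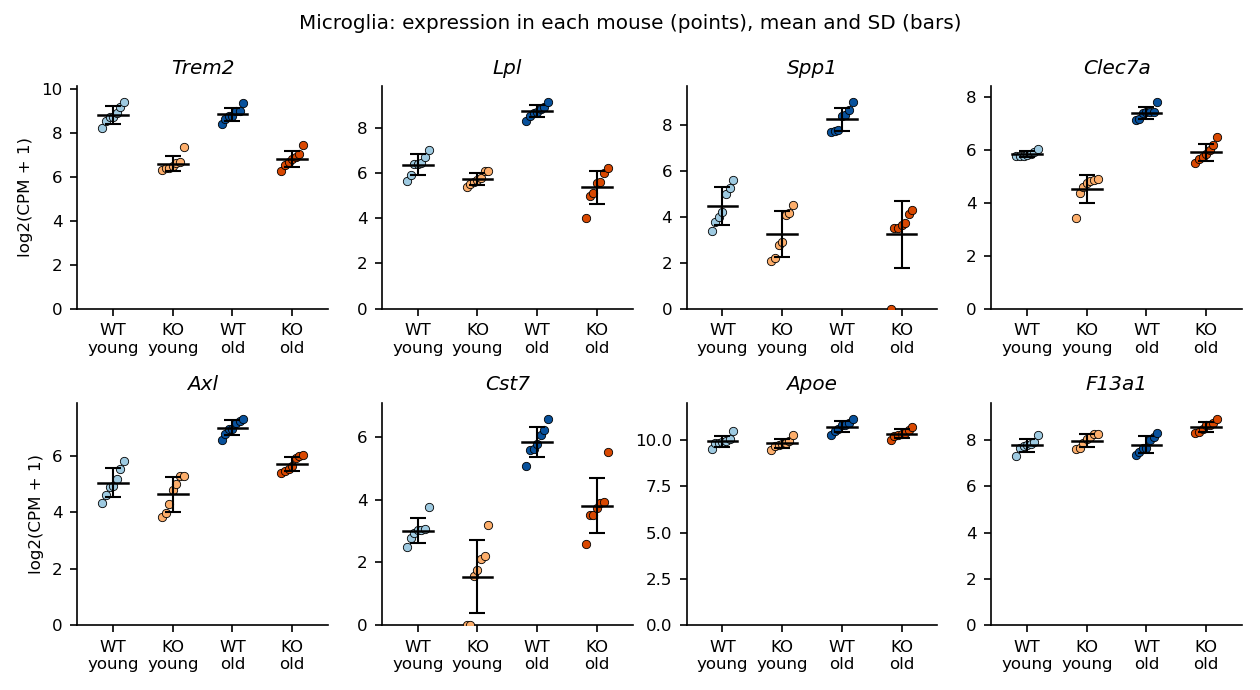
Expression as log2(CPM + 1) on the vertical axes for 8 genes in the 4 microglia groups, with 1 point per mouse and bars for the mean and SD of 7 mice on that scale. Lpl stood at 437 CPM in old WT and 44.9 CPM in old KO microglia, and Spp1 at 325 and 11.3 CPM.

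The interaction asks whether the KO effect differed between ages, and 2 genes were called, with 354 at an unadjusted p under 0.05. The KO effect on Spp1 was larger in old mice by −3.75 ± 0.56 on the log2 scale (adjusted p = 2.5e-04), and that on Lpl by −2.51 ± 0.28 (adjusted p = 7.7e-07). Young microglia held Lpl at 86.4 ± 27.4 CPM in WT and 53.7 ± 10.7 CPM in KO, so the age-related rise was present in WT alone. The same held for Spp1, at 24.6 ± 14.5 and 10.7 ± 7.67 CPM in young mice. Clec7a (−0.27 ± 0.23), Cst7 (−0.39 ± 0.84), Itgax (−0.41), Apoe (−0.27) and Trem2 (0.21) showed no difference past the threshold. The second-stage list was lower (median −0.22, adjusted p = 1.4e-04 with an estimated correlation), with 2 of its genes called and 3 when adjusted over the list alone. Without the filter 25 genes were called.

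In WT microglia, genes of activation were higher and some homeostatic genes lower in old mice. Spp1 rose from 24.6 to 325 CPM (log2 3.90 ± 0.28, adjusted p = 2.1e-12), Lpl from 86.4 to 437 CPM (2.30 ± 0.18, 1.2e-11) and Cst7 from 7.34 to 59.4 CPM (2.99 ± 0.36). Ildr2, an immunoglobulin-like receptor gene (ENSMUSG00000040612.13, chromosome 1, 166254139 to 166316823), rose from 18.5 to 124 CPM (2.76 ± 0.19, adjusted p = 8.3e-13). In total 383 genes were called, 278 higher and 105 lower in old mice, and 1352 had an unadjusted p under 0.05. The other largest rises included the B cell chemokine gene Cxcl13 (4.10 ± 0.72), the immunoglobulin chain gene Igkc (4.02 ± 0.89) and the leukocyte gene Plac8 (2.67). The largest falls were the orphan receptor gene Gpr165 (−2.26), the basement membrane gene Nid2 (−1.52), Rgs7bp (−1.40), Mdfi (−1.39), the small nuclear RNA gene Rn7sk (−1.39), the growth factor gene Hbegf (−1.25), Gpsm1 (−1.18) and Arhgap32 (−1.16). Clec7a (1.57), Axl (1.95), Itgax (2.11) and Apoe (0.79 ± 0.14, 2.8e-04) rose, and Trem2 (0.02), Abca1 (0.01) and Abcg1 (0.08) did not change past the threshold.

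Of the second-stage list 11 of 19 genes were higher in old WT microglia, and 15 when adjusted over the list alone (median 0.74, adjusted p = 1.1e-10 with an estimated correlation). First-stage genes were higher in 7 of 9, among them the ferritin gene Fth1 (1.32), the lysozyme gene Lyz2 (1.07) and B2m (0.62). Of 22 homeostatic genes 6 were lower and 1 higher (8 and 1 when adjusted over the list alone). The falls included the receptor genes Csf1r (−0.50), Mertk (−0.46) and P2ry13 (−0.42), and the rise was Cst3 (0.65). With an estimated correlation that list had an adjusted p = 0.0869. MHC class I genes were higher in 7 of 11, such as H2-Q7 (2.02) and H2-D1 (0.88), with an adjusted p = 0.00409 with an estimated correlation. Of 18 interferon-stimulated genes 3 were higher, and 11 when adjusted over the list alone, among them Ifi27l2a (2.07) and Ifitm3 (0.89); the adjusted p = 0.0744 with an estimated correlation. Ribosomal protein genes were higher in 15 of 23 and positive in all 23 (median 0.65, adjusted p = 3.8e-06 with an estimated correlation), such as Rpl23 (1.16) and Rps24 (1.10). Their share of counts was 1.04 ± 0.148% in young and 1.60 ± 0.0646% in old WT microglia (exact permutation p = 5.83e-04, the smallest possible, adjusted p = 0.0117 over 40 tests). Oxidative phosphorylation genes were higher in 8 of 26, and 13 when adjusted over the list alone, such as Ndufa1 (1.62) and Cox8a (1.15), with an adjusted p = 0.00508 with an estimated correlation. Cholesterol transport genes were higher in 4 of 15, including Soat1 (0.69) and Npc2 (0.48), with an adjusted p = 0.00373 with an estimated correlation.

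Neutrophil markers were higher in 5 of 7 in old WT microglia (median 1.49, adjusted p = 0.0898 with an estimated correlation), among them S100a8 (1.87 ± 0.40) and Camp (2.21). Their summed level was 544 ± 125 CPM in young and 1528 ± 1126 CPM in old WT microglia (exact permutation p = 5.83e-04, the smallest possible, adjusted p = 0.0653). B cell markers, which include Igkc, summed to 317 ± 60.3 CPM in young and 390.5 ± 123 CPM in old WT microglia (exact permutation p = 0.177, adjusted p = 0.545). Monocyte markers, which include Plac8, summed to 156 ± 24.3 and 227 ± 82.7 CPM (exact permutation p = 0.0437, adjusted p = 0.366), and T and NK cell markers to means of 28.2 and 52.2 CPM (exact permutation p = 0.0565, adjusted p = 0.366). By mean log2 level, exact permutation p was 0.0175 for B cell, 0.0297 for monocyte and 0.0122 for T and NK cell markers, with adjusted p = 0.149, 0.208 and 0.149. The share of the mitochondrial ribosomal RNA genes was higher by 2.02 percentage points in old WT microglia (exact permutation p = 0.0122, adjusted p = 0.163). With the neutrophil marker level as a covariate 159 genes were called, 152 of them among the 383.

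Ageing in KO microglia kept many of these changes without the rise of Lpl (44.9 CPM in old against 53.7 CPM in young, log2 −0.22 ± 0.22, adjusted p = 0.781). There were 136 calls, 122 higher and 14 lower in old mice, and 915 genes had an unadjusted p under 0.05. The largest rises were Igkc, Ildr2 (2.96 ± 0.20, adjusted p = 3.5e-13), Cxcl13 (2.95), Cst7 (2.60 ± 0.50), the chemokine gene Ccl8 (2.37), Naalad2 (2.12), the metabolite receptor gene Hcar2 (1.95) and Ly9 (1.87). The largest falls included Gpr165 (−2.55), Rgs7bp (−1.25), Elavl4 (−1.01), Chst7 (−0.93), Adgrl2 (−0.87), the cytokine receptor gene Il7r (−0.87) and Sgk1 (−0.72). Clec7a (from 23.2 to 60.4 CPM), Itgax (1.69) and Apoe (0.52, adjusted p = 0.0371) rose, and Trem2 (0.23) did not change past the threshold.

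Of 18 interferon-stimulated genes 6 were higher in old KO microglia past the threshold, and 17 when adjusted over the list alone (median 0.996, adjusted p = 0.00599 with an estimated correlation), such as Oasl2 (1.24), Ifi27l2a (1.15) and Ifitm3 (1.02). MHC class II genes were higher in 4 of 6, and 6 when adjusted over the list alone, with H2-Aa at 1.21 and H2-Ab1 at 1.19 (adjusted p = 0.00599 with an estimated correlation). B cell markers, of cells that also carry MHC class II and a list that includes Igkc, summed to 302 ± 53.5 CPM in young and 426 ± 92.1 CPM in old KO microglia (exact permutation p = 0.00291, adjusted p = 0.109). Neutrophil markers were higher in 1 of 7, and 6 when adjusted over the list alone (median 1.45, adjusted p = 0.331 with an estimated correlation). MHC class I genes were higher in 5 of 11 (adjusted p = 0.0159 with an estimated correlation). First-stage genes were higher in 6 of 9 and second-stage genes in 6 of 19, or 12 when adjusted over the list alone, with adjusted p = 6.2e-04 and 1.3e-06 with an estimated correlation. Ribosomal protein genes were higher in 8 of 23, and 16 when adjusted over the list alone (median 0.58, adjusted p = 7.6e-06 with an estimated correlation). Calls ranged from 103 to 190 when single libraries were left out, and numbered 225 without the filter, 244 with limma-voom and 243 with numbering sets as a covariate.

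The ageing effects of the genotypes, which share no libraries, went largely the same way. Of the 383 genes called in WT microglia 371 had the same sign in KO, and of the 136 called in KO 135 had the same sign in WT. Both sets shared 82 rises, where 4.52 were expected by chance, and 9 falls, where 0.196 were expected. No gene was called in opposite directions. Across the 7512 genes, which are not independent replicates, Pearson's r was 0.55 and Spearman's rho 0.42. Only Spp1 and Lpl differed past the threshold in the interaction test, so a gene called in 1 genotype alone is not shown to differ between them.

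**Figure D2:**
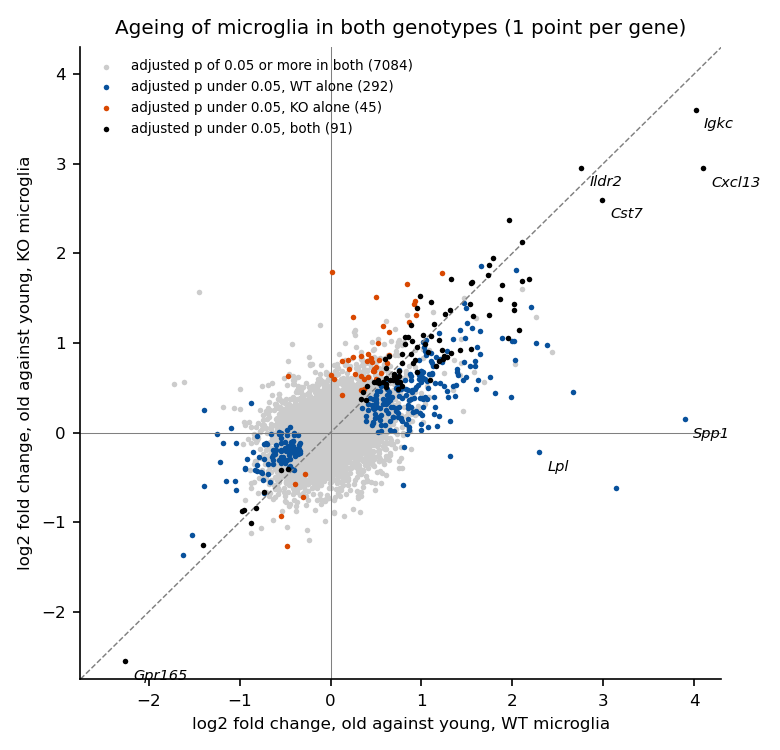
Log2 fold change of old against young microglia in WT mice (horizontal axis) and KO mice (vertical axis), 1 point per gene tested, coloured by the genotype in which the adjusted p was under 0.05, with a dashed line where both are equal. Spp1 and Lpl, at 3.90 and 2.30 in WT, lie away from the diagonal, while Ildr2 was at 2.76 in WT and 2.96 in KO.

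**Figure D3:**
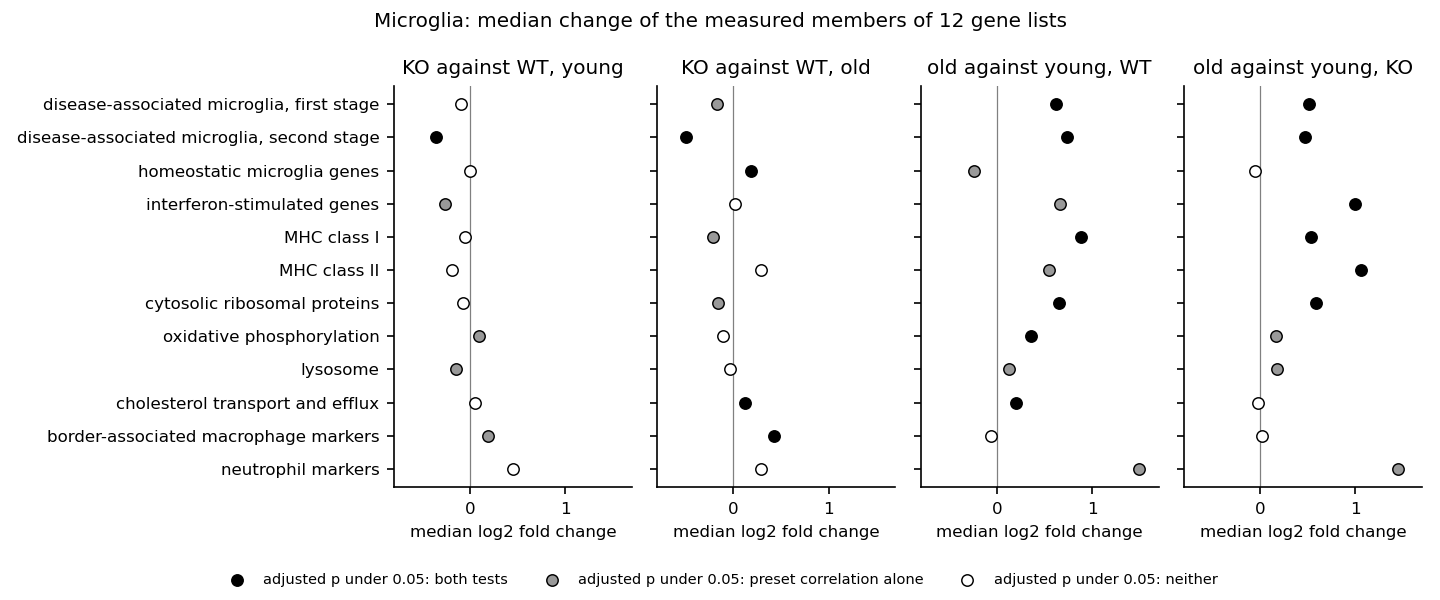
Median log2 fold change (horizontal axes) of the tested members of 12 gene lists in 4 microglia comparisons, with black points for lists past the threshold at the preset and the estimated correlation, grey for the preset alone and white for neither. The second-stage list of disease-associated microglia lies at 0.74 for ageing in WT, 0.47 for ageing in KO and −0.50 for KO against WT in old microglia.

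In astrocytes, loss of Trem2 changed no gene past the threshold at either age. The reactive gene Gfap stood at 41.5 CPM in young WT, 40.9 in young KO, 49.4 in old WT and 38.2 CPM in old KO astrocytes (log2 −0.02 in young and −0.32 in old mice). Serpina3n was at 27.8 CPM in old WT and 40.1 CPM in old KO astrocytes (0.55 ± 0.26, adjusted p = 0.973), and Apoe at 3744 and 3637 CPM (−0.04). edgeR called 0 genes in young astrocytes, with 246 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well. In old astrocytes edgeR called 0, with 379 at an unadjusted p under 0.05, and DESeq2 and limma-voom again called 0. Without the filter 6 genes were called at each age, and 3 in old astrocytes with a copy-to-parent covariate. No list was called in young astrocytes. In old astrocytes the list of transport and coupling genes was negative in 14 of 16 (median −0.18), with an adjusted p = 0.504 with an estimated correlation, and astrocyte markers were lower (median −0.22), with an adjusted p = 0.119 with an estimated correlation. On simulated data 72.7% of 2-fold changes were found at this depth, but with many genes changed at once. With few changed genes the adjusted threshold is stricter, so that share does not apply here. Effects of 2-fold and smaller ones could have been missed.

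With the settings used throughout, ageing changed 2 single astrocyte genes in WT and 3 in KO, and with numbering sets as a covariate 14 and 20. In WT astrocytes the metalloprotease gene Adamts1 fell from 76.5 to 30.95 CPM (log2 −1.27 ± 0.25, adjusted p = 0.0404) and the transferrin receptor gene Tfrc from 105 to 57.3 CPM (−0.89 ± 0.18, 0.0404). These were the 2 calls (6 with DESeq2 and with limma-voom, 52 without the filter), with 538 genes at an unadjusted p under 0.05. In KO astrocytes the interferon-stimulated gene Ifit1 rose from 6.53 to 28.3 CPM (2.14 ± 0.35, 0.00276), and the glutamate receptor gene Grm5 fell from 39.9 to 10.4 CPM (−1.92 ± 0.32, 0.00276). The remaining 1 of 3 calls, AC149090.1, is an unnamed clone outside the naming rule, chosen after its values were seen (1.36 ± 0.25, 0.00897), and 553 genes had an unadjusted p under 0.05. Gfap (0.21 in WT and −0.09 in KO) and Apoe (0.17 and 0.20) did not change past the threshold. C4b was at 3.95 and 11.1 CPM in young and old WT, and at 6.88 and 13.7 CPM in young and old KO astrocytes, without a call.

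For astrocyte ageing 9 gene lists were called in WT and 7 in KO at the preset correlation, and 2 and 3 with an estimated one. Interferon-stimulated genes were higher in old WT astrocytes, with 0 of 9 past the threshold and 7 when adjusted over the list alone (median 0.84, adjusted p = 0.00952 with an estimated correlation). In KO astrocytes 1 was past the threshold and 3 when adjusted over the list alone (median 0.65, adjusted p = 0.00168 with an estimated correlation). Glycolysis and hypoxia genes were higher in old WT astrocytes (median 0.30, adjusted p = 0.0211 with an estimated correlation) and had an adjusted p = 0.0557 in KO. MHC class I genes were higher in KO astrocytes (median 0.41, adjusted p = 0.00655 with an estimated correlation). Microglia markers, from cells that also express interferon-stimulated genes, were positive in all 11 tested in old WT astrocytes, with 0 called (median 0.36, adjusted p = 0.603 with an estimated correlation). Their median was 0.44 with numbering sets as a covariate and 0.63 with RIN (adjusted p = 0.00877 and 0.0134 at the preset correlation). Mural cell markers (median −0.71) and ependymal markers (median −0.43) were lower in old WT astrocytes, with adjusted p = 0.0790 and 0.123 with an estimated correlation. Oligodendrocyte markers were lower as a list in old WT astrocytes, with 6 of 11 lower when adjusted over the list alone (median −0.96, adjusted p = 0.0790 with an estimated correlation), and in KO also 6 (median −0.65, adjusted p = 0.199 with an estimated correlation). Their summed level was 9014 ± 3876 CPM in young and 4933 ± 3319 CPM in old WT astrocytes, and 8828 ± 4742 and 5583 ± 3543 CPM in KO. Neither summed fall passed the exact permutation test (p = 0.0565 and 0.163, adjusted p = 0.366 and 0.537). By mean log2 level, exact permutation p was 0.0152 in WT and 0.101 in KO, with adjusted p = 0.149 and 0.403. RIN was 9.31 in young and 8.51 in old WT astrocytes (exact permutation p = 0.0280, adjusted p = 0.261), and with RIN as a covariate Adamts1 (−1.18, adjusted p = 0.286) and Tfrc (−0.98, adjusted p = 0.166) were not called, though their folds were close to those without it. Leaving out single libraries gave 0 to 9 calls in WT, with 0 without any 1 of 16 libraries, and 3 to 8 in KO.

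**Figure D4:**
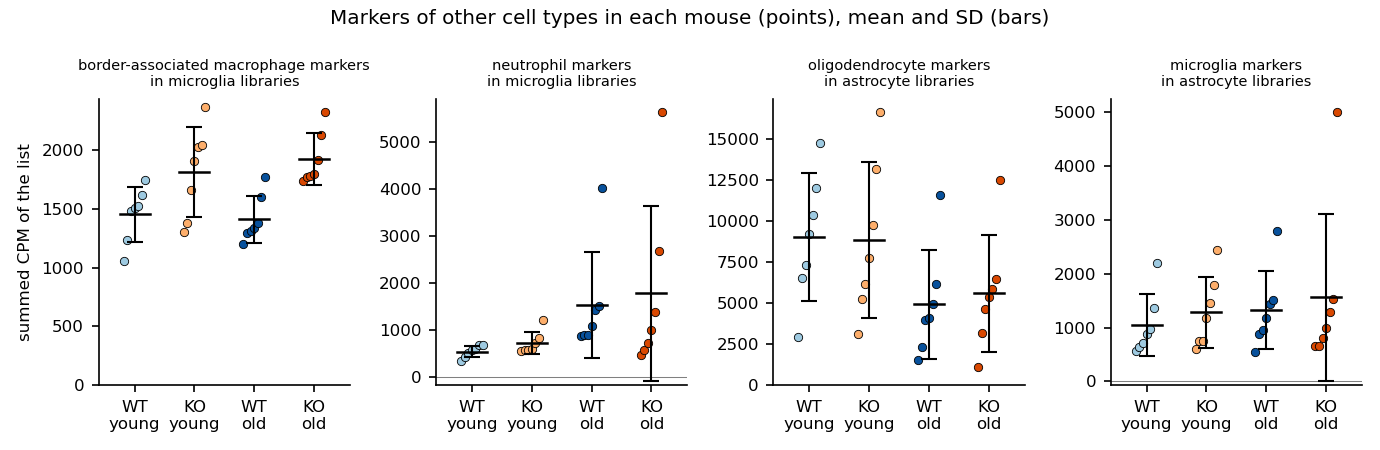
Summed CPM (vertical axes) of 4 marker lists of other cell types in microglia or astrocyte libraries of each group, with 1 point per mouse and bars for the mean and SD of 7 mice. Oligodendrocyte markers averaged 9014 CPM in young and 4933 CPM in old WT astrocytes, and border macrophage markers 1413 CPM in old WT and 1924 CPM in old KO microglia.

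The genotype by age interaction in astrocytes was called by edgeR for 0 genes, with 302 at an unadjusted p under 0.05. DESeq2 called 0 and limma-voom 1, and edgeR called 1 with numbering sets as a covariate (Igfbp4), 2 without the filter and 1 without old WT animal 3. Astrocyte markers were lower as a list, by a median of −0.25, with an adjusted p = 0.136 with an estimated correlation. The differing calls of the ageing comparisons in WT and KO astrocytes are thus not shown to differ between genotypes.

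The comparison of microglia with astrocytes checks that the sorts hold the cells their labels name. All 22 homeostatic microglia genes were higher in microglia, and all 16 astrocyte markers were higher in astrocytes, such as Aldoc (log2 −5.84). In total 7922 of 9434 genes were called, 4038 higher in microglia and 3884 higher in astrocytes, and 7974 had an unadjusted p under 0.05. With RLE scaling 3737 were higher in microglia and 4130 in astrocytes, and with DESeq2 3732 and 4129, so which side holds more genes depends on the scaling. The largest differences towards microglia were Csf3r (6.91), Tagap (6.41), Asb2 (6.40), Gmfg (6.26), Irf5 (6.24), Bin2 (6.24), Spint1 (6.09) and Fcgr1 (6.05). Towards astrocytes they were Lcat (−6.57), Nkain4 (−6.51), Gdpd2 (−6.29), Sfrp5 (−6.20), Fgfr3 (−6.15), Arxes1 (−6.13), Slc38a3 (−6.10) and Ddo (−6.07). Of 20 cholesterol biosynthesis genes 19 were higher in astrocytes (median −2.72), such as Sqle (−4.61), and Apoe was higher there too (−1.75). All 23 ribosomal protein genes (median 1.97), 27 of 32 lysosome genes and all 20 immediate early genes (median 4.35) were higher in microglia. Microglia markers summed to 53650 ± 3342 CPM in microglia and 1304 ± 924 CPM in astrocytes (SD, n = 28).

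Differences between the cell types in the KO effect were tested in all 56 libraries. In old mice 4 genes were called, with 421 at an unadjusted p under 0.05. The KO effect in microglia was lower than in astrocytes for Spp1 (log2 −4.80 ± 0.89, adjusted p = 0.00878), Lpl (−3.16 ± 0.64, 0.0199), Ifi27l2a (−2.67 ± 0.52, 0.0128) and Axl (−1.26 ± 0.26, 0.0229). Axl is expressed in both cell types, at 83.6 to 93.5 CPM in the astrocyte groups. For the interferon-stimulated gene Ifi27l2a the astrocyte levels were low, with 2.16 CPM in old WT and 13.8 CPM in old KO, against 73.5 and 57.97 CPM in microglia. Trem2 (−2.54 ± 0.66, adjusted p = 0.347) was not past the threshold, at astrocyte levels of 5.71 CPM in old WT and 9.34 CPM in old KO, the latter raised by animal 12 (35.5 CPM), whose library also held 4989 CPM of microglia markers. Second-stage genes were lower as a list, with 3 of 20 called and 9 when adjusted over the list alone (median −0.65, adjusted p = 5.2e-06 with an estimated correlation). In young mice edgeR called 0 genes, with 396 at an unadjusted p under 0.05, and DESeq2 called 0. Without the filter 1 was called.

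The ageing effect in WT mice differed between the cell types for 58 genes, 46 higher and 12 lower in microglia, with 982 at an unadjusted p under 0.05. The largest differences were Spp1 (4.37), Crip1 (3.12), Ifi27l2a (3.11), Ildr2 (2.77 ± 0.24, adjusted p = 1.4e-13), the lipid carrier gene Fabp5 (2.62), Fn1 (2.60), Mllt4 (2.33) and Rps18 (2.07). On the other side were Ephb3 (−1.86), Hbegf (−1.69), St6galnac4 (−1.69), Trim30d (−1.52), Hfe (−1.29), Rgs7bp (−1.27), Pdlim4 (−1.23) and Arhgap32 (−1.16). Second-stage genes rose more in microglia, 5 past the threshold and 11 when adjusted over the list alone (median 0.94, adjusted p = 8.9e-06 with an estimated correlation). So did ribosomal protein genes, with 7 past the threshold and 13 when adjusted over the list alone (median 0.92, adjusted p = 3.8e-06 with an estimated correlation). With the animal as a block 98 genes were called, 55 of them among the 58.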

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

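The tests of the differences between ages and between cell types were planned. Of the tests in this part, leaving out the libraries that correlated least with their own group was chosen after the data were seen. The difference in the KO effect between old and young microglia was past the threshold for 2 genes, Lpl (log2 −2.51 ± 0.28) and Spp1 (−3.75 ± 0.56). Of 100 splits 1, the real one, gave 2 genes, and the highest other gave 1. The splits exchanged KO and WT labels within each age, and so also removed any KO effect shared by both ages. They therefore cannot exclude chance for a difference between the ages. Lpl stood at 53.7 CPM in young and 44.9 CPM in old KO microglia, and Spp1 at 10.7 and 11.3 CPM, so neither showed the rise with age seen in WT.

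Between cell types, the KO effect in old mice differed for 4 genes and the ageing effect in WT mice for 58 genes. In each case 1 of 100 splits, the real one, gave as many, and the highest other gave 1. The splits exchanged whole mice, and so also removed any effect shared by the cell types. They therefore cannot exclude chance for a difference between the cell types. These comparisons set a cell type with many Trem2 counts against one with few, and the 4 genes include Ifi27l2a, at 2.16 CPM in old WT astrocytes.

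Some single libraries stood apart from the other 6 of their group, in 12 of 84 sets of 7 values looked at. Dixon's outlier test would give 4.2 by chance if the values were independent and normally distributed. The sets share libraries and many values are CPM, which can be skewed, so an excess over chance is not shown. In old KO microglia the ribosomal protein share was 1.16% in animal 20, with the nearest other at 1.45%, and Cst7 was 45.5 CPM in animal 12, with the nearest at 14.2. In young WT microglia Cst7 was 12.6 CPM in animal 21, with the nearest at 7.29. Trem2 was 162 CPM in the young KO microglia of animal 6, with the nearest at 100.2, which is still below every WT library. Clec7a was 220.2 CPM in the old WT microglia of animal 7, with the nearest at 173. Summed neutrophil markers were 1218 CPM in the young KO microglia of animal 6, 4010 in the old WT microglia of animal 23 and 5624 in the old KO microglia of animal 28. The nearest others of those groups were at 832, 1515 and 2677 CPM.

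In old KO astrocytes animal 12 correlated least with its own group (0.753, nearest 0.885) and held 4989 CPM of microglia markers, with the nearest at 1535. In old WT astrocytes animal 7 correlated at 0.777 with its group, with the nearest at 0.867, and its copy-to-parent score was 1.03, with the nearest at −0.0479. The astrocyte ageing calls in WT numbered 1 without these libraries, and the other astrocyte counts were within 1.5 times their values with them. In microglia the library left out was that of old KO animal 8 (0.854), and the microglia libraries named above were kept. No explanation of a single library was tested.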

How the results depend on the processing

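Alternatives added after the data were seen include fits without the libraries that correlated least with their own group. These were the old KO astrocytes of animal 12, old WT astrocytes of animal 7 and old KO microglia of animal 8. Others left out animals 5 to 8 or the mitochondrial ribosomal RNA genes. The rest were the copy-to-parent, border macrophage, neutrophil and oligodendrocyte covariates. Of the counts of genes or lists under alternatives other than leaving out 1 library, 99 stayed within 1.5 times and 37 did not. For the 283 named results past the threshold, 5245 alternative values were had. Of these, 4991 stayed past it, 254 were lost and 0 reversed, and 232 results were past it under every alternative. Of the 42 followed but not past it, 3 values of 1544 were past it under an alternative. Among the 283, those from comparisons between cell types had only RLE, no filter, DESeq2 and the animal as a block as alternatives. They thus had fewer chances to be lost than those within a cell type. No scaling moved the median of all genes by over 0.1 on the log2 scale, the most being −0.0895 for microglia against astrocytes with DESeq2. Unless stated, the cause of a change was not tested.

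Without the filter, more low-count genes entered and calls were 63 for KO in young microglia, 26 in old microglia, 225 for ageing in KO microglia and 25 for the microglia interaction. For KO in astrocytes they were 6 in young and 6 in old mice, for ageing 52 in WT and 35 in KO, and for the interaction 2. Microglia against astrocytes gave 13834, and the KO effect between cell types in young mice gave 1. DESeq2 gave 16 for KO in old microglia, and 6 and 9 for astrocyte ageing in WT and KO. Limma-voom gave 244 for ageing in KO microglia, 6 and 5 for astrocyte ageing in WT and KO, and 1 for the astrocyte interaction. Numbering sets as a covariate gave 7 and 16 for KO in young and old microglia, 243 for ageing in KO microglia, 14 and 20 for astrocyte ageing in WT and KO, and 1 for the astrocyte interaction (Igfbp4). Only the 2 groups compared gave 2 for KO in young microglia and 7 for astrocyte ageing in WT. RIN as a covariate gave 0 for astrocyte ageing in WT. The copy-to-parent covariate gave 18 for KO in old microglia, 223 for ageing in KO microglia and 3 for KO in old astrocytes. The border macrophage covariate gave 2 and 6 for KO in young and old microglia, the 6 being Axl, Clec7a, Lpl, Spp1, St8sia6 and Trem2. The neutrophil covariate gave 159 for ageing in WT microglia. Astrocyte ageing in WT gave 1 without the libraries that correlated least with their group and 0 without animals 5 to 8, which leaves fewer mice. The animal as a block gave 98 for the ageing effect between cell types, and moved no other count of genes beyond 1.5 times.

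Leaving out 1 library gave 2 to 5 calls for KO in young microglia, 8 to 13 in old microglia, 280 to 427 and 103 to 190 for ageing in WT and KO microglia, and 2 to 3 for the microglia interaction. KO in astrocytes stayed at 0. Astrocyte ageing gave 0 to 9 in WT, beyond 1.5 times for 23 of 28 libraries and 9 without old WT animal 27. In KO it gave 3 to 8, with 5 without old KO animal 16, 8 without old KO animal 20 and 5 without young KO animal 22. The astrocyte interaction gave 0 to 1, with 1 without old WT animal 3. Adamts1 was lost in 21 and Tfrc in 19 of 40 alternatives. Of 431 list tests 109 were called at the preset correlation and 50 with an estimated one, and fry called 85, 72 of them in both.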

Other observations

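Effects pooled over both ages or both genotypes were chosen after the data were seen, and so were the copy-to-parent score, the permutation of set and group labels and the test of genes near Trem2. The other tests in this part were set out before their results were seen. Pooled over ages, KO microglia differed in 17 genes, 1 higher and 16 lower. Beyond the genes called at a single age these included the growth factor gene Csf1 (log2 −0.99 ± 0.19, adjusted p = 0.00489), the receptor gene Slamf8 (−1.22, 0.00703) and the lysosomal membrane gene Cd63 (−0.52, 0.0401). In astrocytes the pooled KO effect called 0 genes with edgeR, with 305 at an unadjusted p under 0.05. Of the 16 falls in microglia, 8 were second-stage genes of disease-associated microglia.

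Pooled over genotypes, ageing called 674 microglia genes, 463 higher and 211 lower, with Ildr2 at 2.86 ± 0.14 (adjusted p = 6.3e-18), Lgals3 at 1.62 and Tnfsf13b at 1.34. Interferon-stimulated genes were higher in 14 of 18 (adjusted p = 0.00905 with an estimated correlation). In astrocytes pooled ageing called 35 genes, 16 higher and 19 lower. The rises included the interferon-stimulated genes Ifit1 (1.61) and Rsad2 (1.07), and the falls Grm5 (−1.34), Adamts1 (−1.03), Tfrc (−0.81) and the oligodendrocyte genes Cldn11 (−1.37), Ugt8a (−1.39) and Mal (−0.98).

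Border macrophage genes were higher in old KO than in old WT microglia (median log2 0.43), and the border macrophages are Cd11b-positive cells that the sort would not remove. A shift in library scaling was not tested, since TMM centres the typical gene. If the share of these cells in a sort varied, their markers would move together within groups, and the mean correlation between members was 0.259 ± 0.0692, against an upper bound of 0.119 for random lists. That lies between the bounds set for and against this explanation, so a larger share of border macrophages cannot be told apart from a change in expression. The abundant members Mrc1 (0.43 ± 0.19) and Pf4 (0.45 ± 0.18) moved by a like amount, and an effect of genotype on expression stays open and may add to it.

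Ribosomal protein genes were higher in old than in young WT microglia, by a median of 0.651 ± 0.133 with 15 genes called. Here ± is the spread of the median over resampled list members, which are not independent, and not over mice. Reads counted on rows named as copies are argued against, since adding 39 such rows to their parents left the median at 0.630 ± 0.113 with 15 called. Copies under other names were not added, so reads shared with those were not tested. RIN averaged 9.64 in young and 9.81 in old WT microglia (exact permutation p = 0.633, adjusted p = 0.902). As a covariate it thus had little to correct (0.636 ± 0.131, 13 called) and does not decide on RNA integrity. Neutrophils, B cells, and T and NK cells are argued against by 0.623 ± 0.105, with their 3 marker levels as covariates and 8 called. Monocyte markers were not among these covariates. The numbering sets hold 1 mouse of every group, so a difference between sets cannot shift a median between ages. Within every set the numbers ran in the order young WT, young KO, old WT, old KO. An effect of that order cannot be told apart from age or genotype, and library or sequencing batches are not given in the labels. A biological effect of age may explain the rise and stays a hypothesis.

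Oligodendrocyte genes were lower in old than in young astrocytes, and they moved together between libraries of the same group, with a mean correlation of 0.603 ± 0.0639 against an upper bound of 0.124 for random lists. Less oligodendrocyte RNA carried into the old sorts, which the ACSA-2 sort should largely remove, is therefore a candidate explanation. The abundant member Mbp did not share the fall in WT, at −0.06 ± 0.27, and an effect of age on these cells was not tested. With RIN as a covariate the median over both genotypes was −0.611 ± 0.169, against −0.814 ± 0.192 without, and called genes went from 3 to 0 as the fold shrank. Again ± is the spread over resampled list members and not over mice. The median with RIN is within this spread of the bound set against RNA integrity, so a part played by it stays open.

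Libraries also differed in a way the groups do not explain. The first principal component held 24.6% of the variance in microglia and 30.7% in astrocytes. Sets of 4 consecutive animal numbers, each with 1 mouse of every group, accounted for 0.458 and 0.624 of it, where shuffled sets gave a mean of 0.222 and 0.223 (permutation p = 0.0321 and 0.00251). The groups accounted for 0.177 and 0.0892, where shuffled groups gave 0.111 and 0.111 (permutation p = 0.189 and 0.525). The copy-to-parent score, which compares processed copies with their parent genes in 12 pairs, averaged 0.890 in the microglia of animals 5 to 8 and 0.105 in the others, and 0.626 and −0.358 in astrocytes. The ranges overlapped, with others as high as 1.14 in microglia and 1.29 in astrocytes, and with 0.174 the lowest astrocyte score of animals 5 to 8. The sets are balanced over the groups, and the labels do not call them batches. The order of the groups was the same within every set, so an effect of order cannot be told apart from the groups. Genes within 10 Mb of Trem2 had an unadjusted p under 0.05 more often than others in microglia (9 of 67, with 4.12 expected, Fisher's exact p = 0.0353), and none was called.

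Splits of the same samples into other groups of the same sizes show whether chance can be excluded, over 100 splits with the real one included. For KO in young microglia 1 split gave as many genes as the real 4, and the highest other gave 1. For KO in old microglia it was 1, with 10 real and 3 highest other. For ageing it was 1 in WT microglia, with 383 real and 46 highest other, and 1 in KO, with 136 and 8. For microglia against astrocytes, where labels were exchanged within mice, it was 1, with 7922 and 2691. For astrocyte ageing it was 1 in WT, with 2 real and 1 highest other, and 2 in KO, with 3 real and 16 highest other. Chance can be excluded for ageing in microglia and for microglia against astrocytes, by splits that ignore the numbering sets. For KO in microglia it can be excluded only for counts that include Trem2, the targeted gene, whose call follows from the genotype labels. The splits were not counted without Trem2, so they do not exclude chance for KO effects beyond it. In young microglia the count also fell to 2 without any 1 of 4 libraries. For astrocyte ageing the share of splits is also under 0.05. The few calls there are not firm, since the WT count was 0 without any 1 of 16 libraries and another split gave more genes than the real one in KO. For the comparisons with 0 genes all 100 splits gave as many by construction, which says nothing about chance, and the highest others were 1 for KO in young astrocytes, 237 in old astrocytes, 0 for the astrocyte interaction and 7 for the KO effect between cell types in young mice. The split with 237 genes divided old astrocytes almost wholly along the numbering sets, which points to a structure of the samples, and with the sets as a covariate the real comparison still called 0.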
